A study of Mus musculus with 12 samples.

How the data were processed

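RNA was sequenced from 12 sorted cell samples of mouse hearts with a myocardial infarction. Per the labels, the mice carried a p16-2A-CreER allele, which makes a tamoxifen-dependent Cre recombinase from the p16 locus, and the R26-mTmG reporter, which switches a cell from red to green fluorescence once Cre has acted. Tamoxifen was given on day 5 after infarction and the infarct zone was taken on day 7. Cardiomyocytes were removed, and the remaining cells were sorted by antibodies against PDGFRα, a surface receptor of fibroblasts, or F480, the macrophage surface protein that Adgre1 encodes, and by high or low green fluorescence. High and low green fluorescence are called P16hi and P16lo here. Each of the 4 groups held 3 samples, numbered as in the labels. The labels do not say whether samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

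Per the labels' protocols, RNA was reverse transcribed, the cDNA was fragmented and tagged by a transposase, and the libraries were sequenced as DNA nanoballs by probe-anchor chemistry. HISAT and the mouse builds GRCm38 and mm10 are named in the submitters' processing notes. The HISAT version and the counting tool are not given in the sources used here, nor is whether strand was used, so genes that overlap on opposite strands, and near-identical copies such as the hemoglobin genes, carry uncertain counts. Each sorted population came as a separate table. Per the file headers, the authors deposited estimated counts, FPKM, TPM and a normalised read count for each library and gene. The estimated counts were not whole in 13.0% to 19.2% of values, which the counting of shared reads can give. The deposited TPM sum to 1000000 in each library. The deposited normalised read counts, read here as a signal, equal the count, rounded up, times 1 factor per library and were not used in any comparison. FPKM served only to check the TPM.

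Each table held a pair of column blocks side by side, each with its own gene order and its own set of listed genes. Values were joined by gene identifier, and a gene listed for only 1 block was set at 0 in the other. For PDGFRα 13053 of 17398 genes were listed in both blocks, and for F480 15698 of 17071. The rule of setting unlisted genes at 0 was chosen after the tables were seen and before any model was fitted. The PDGFRα table lists P16hi library 1 in a block of its own. For F480, a block holds P16lo library 3 with P16hi libraries 2 and 3, and the other holds P16lo libraries 1 and 2 with P16hi library 1. The labels do not say what the blocks stand for. Of 17952 gene identifiers, 17900 (99.7%) matched the GRCm38.p6 annotation, from which coordinates were taken.

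Total counts per library ran from 3.16 M to 27.9 M (M, 1000000 counts). Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, libraries were scaled by TMM, and a robust quasi-likelihood F-test compared P16hi with P16lo within each sorted population. A further edgeR fit of all 12 libraries tested whether the difference itself differed between PDGFRα-high and F480-high cells. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM are counts per 1000000 of the TMM-scaled library size, so the summed CPM of an abundant list can exceed its share of the raw counts. Cdkn2a, Ccl8, Pdgfra and Adgre1 were also compared by exact two-sided permutation tests on log2(CPM + 1), whose smallest possible p with 3 against 3 libraries is 0.1. The pooled Cdkn2a ratio has an exact binomial 95% interval, which covers counting error only.

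A set of 36 gene lists, for cell types, processes and pathways, was fixed before the data were examined, as were the comparisons, the main tests, the other settings and the rule for naming genes. Lists with at least 5 tested members were tested with camera from limma 3.58.1 with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry. The list of genes encoded by mitochondrial DNA had 0 members in the tables and was not tested. Genes were named by this rule. Cdkn2a and Ccl8 were always named, as the gene of the sort reporter and of the series title, with Pdgfra and Adgre1 as sort checks. With no gene past the threshold, the 3 genes of smallest p in each direction were taken among those with a mean log2 CPM of at least 3 whose P16hi and P16lo libraries did not overlap, leaving out predicted genes, and without the overlap condition for the difference between populations. A gene that this rule selected for that difference is not reported here. From each list, any of the 3 members with the smallest p could be named, and which of these are printed was chosen after their values were seen.

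The other settings were other scalings (DESeq2's size factors in edgeR, upper quartile, library totals only), no low-count filter, at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, no robust step, the replicate number as a block, an absolute log2 fold change of at least 1, a fit of all 12 libraries, and leaving out each library in turn. Settings added after the data were seen were only genes listed in both blocks, the column block of the F480 table as a covariate, removal of the hemoglobin genes and Gm20594, limma on log2(TPM + 1) with a TPM of at least 1 in at least 3 libraries and a pseudocount of 1 (its F480 fit uses the TPM of P16hi library 3, which do not follow that library's FPKM), and leaving out a pair of libraries that stood apart (P16lo 1 and P16hi 1 of PDGFRα, P16lo 3 and P16hi 3 of F480). The overlap between populations was also recomputed without each library. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

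The edgeR and camera steps were tested on simulated data. At the spread of the PDGFRα libraries 49.2% of the 16-fold changes were called, with 0 of the 4-fold and 0 of the 2-fold changes, among 12933 tested genes. At the spread of the F480 libraries 43.1% of the 16-fold changes and 0 of the smaller ones were called among 12179 genes. For the difference between populations the shares were 28.8% at 16-fold and 3% at 4-fold among 13801 genes, with 2 false calls, where the other fits had 0. At a low spread 95.5% to 100% of the 4-fold changes were called, with 12 false calls among 204, 8 among 216 and 6 among 176. Camera called the 1 changed list and 0 of 30 unchanged lists in each simulation. Genes were simulated as independent of one another, so these runs could not show false calls of lists whose genes vary together. In the data the median estimated correlation within lists was 0.5 in PDGFRα-high and 0.535 in F480-high cells.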

Results

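The series profiled bulk RNA of cells sorted from the infarct zone of mouse hearts on day 7 after infarction. Green fluorescence marked cells whose p16 locus had been active around the tamoxifen dose on day 5, and the series title asks about Ccl8 in P16-positive cells. The 12 libraries formed 4 groups of 3: P16lo and P16hi cells with high PDGFRα, and P16lo and P16hi cells with high F480. In PDGFRα-high cells the P16lo libraries 1 to 3 held 18.9, 15.7 and 13.5 M counts (M, 1000000) and the P16hi libraries 3.16, 5.07 and 10.2 M. In F480-high cells the P16lo libraries held 26.3, 27.7 and 22.9 M and the P16hi libraries 27.9, 24.1 and 15.5 M.

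Cdkn2a, the gene of the p16 cell cycle inhibitor, was higher in each P16hi library than in every P16lo library of both populations, on few counts. Its locus (gene 12578, chromosome 4, 89274473 to 89294619, GRCm38) also encodes p19Arf, and the counts do not separate the products. In PDGFRα-high cells Cdkn2a had 2, 2 and 3 counts in the P16lo libraries and 6, 5 and 8 in the P16hi libraries, a pooled CPM ratio of 5.3 (95% interval 2.13 to 14.9). In F480-high cells it had 4, 5 and 3 counts against 13, 26 and 14, a ratio of 5.02 (2.65 to 10.3). There Cdkn2a had a log2 fold change of 2.28 and did not pass edgeR. With no low-count filter, it had 2.47 (SE 1.42, edgeR adjusted p = 0.82) in PDGFRα-high cells. In F480-high cells this setting gave 2.25 (SE 1.22, edgeR adjusted p = 0.97), so neither difference passed. The exact permutation p was 0.1 in each population, the smallest that 3 against 3 libraries can give, and the intervals cover counting error only.

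The genes of the sort antibodies overlapped between P16hi and P16lo libraries in both populations. Pdgfra (gene 18595, chromosome 5, 75151322 to 75198206) had 4.65, 6.76 and 165 CPM in the P16lo and 20.2, 8.61 and 46.5 CPM in the P16hi libraries of PDGFRα-high cells, and a mean of 1.37 ± 0.805 (SD, n = 3) and 2.46 ± 1.47 (n = 3) CPM in F480-high cells. Adgre1, which encodes F480 (gene 13733, chromosome 17, 57358581 to 57483529), had 772, 52 and 28.7 CPM in PDGFRα P16lo and 255, 221 and 135 CPM in PDGFRα P16hi cells. In F480-high cells it had 1140, 1590 and 33.5 CPM in P16lo and 1800, 226 and 360 CPM in P16hi libraries. In the PDGFRα sorts macrophage markers summed to 33620, 9978 and 2523 CPM in P16lo and 20340, 15270 and 7008 CPM in P16hi libraries 1 to 3. Fibroblast markers summed to 778, 2814 and 22910 CPM and to 4811, 2048 and 7829 CPM. They were below the macrophage markers in P16lo 1 and 2 and P16hi 1 and 2. The lists hold different genes, so their sums are not shares of cells. Differences in PDGFRα-high cells cannot be assigned to fibroblasts alone. The populations came in separate tables, and levels across them are only set side by side.

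**Figure D1:**
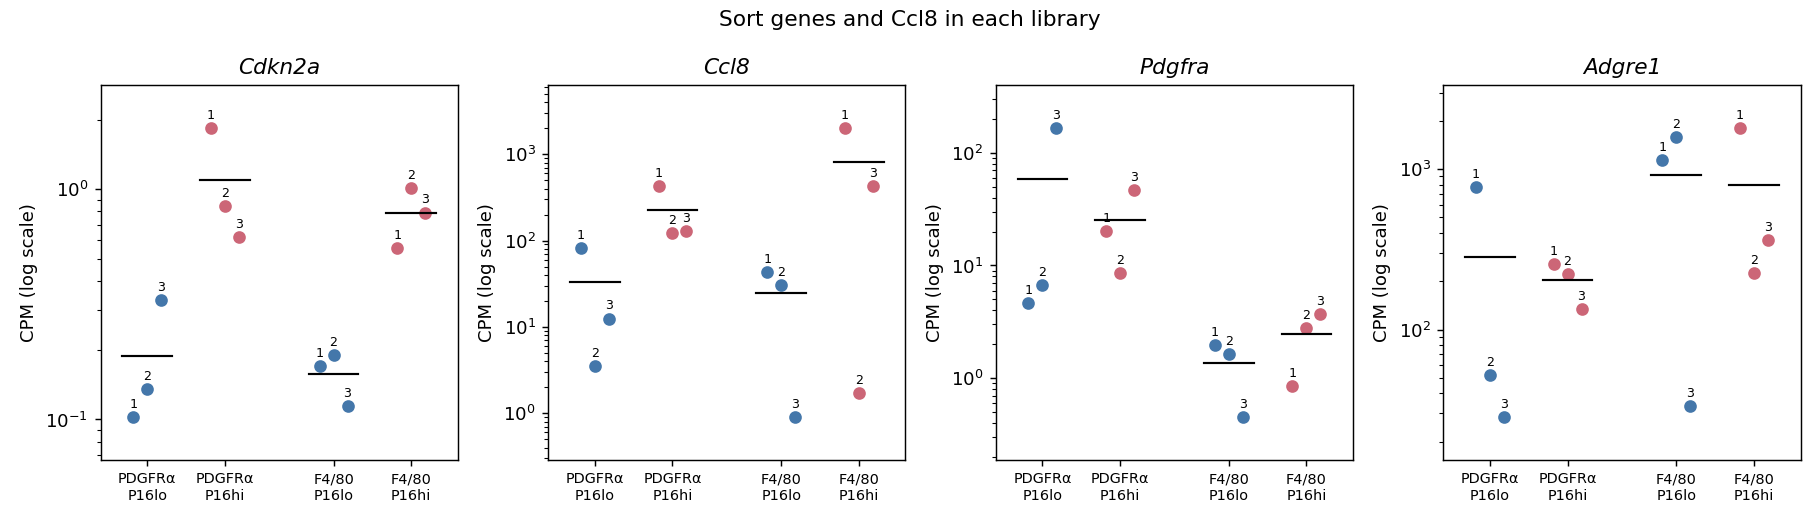
CPM on a log scale of Cdkn2a, Ccl8, Pdgfra and Adgre1 in each of the 12 libraries, as points numbered by replicate, with a line at the mean of each group of 3. Cdkn2a and, in PDGFRα-high cells, Ccl8 had each P16hi library above each P16lo library; Ccl8 in F480-high cells ran from 0.916 to 2000 CPM.

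In PDGFRα-high cells, Ccl8 was higher in each P16hi library than in every P16lo library. Ccl8, a chemokine that draws monocytes and lymphocytes (gene 20307, chromosome 11, 82115185 to 82116799), had 82.9, 3.52 and 12.5 CPM in P16lo and 429, 123 and 128 CPM in P16hi cells, with means of 33.0 ± 43.5 and 227 ± 175 (SD, n = 3). Its log2 fold change was 2.78 (SE 1.14), with an edgeR adjusted p of 0.746, so the difference did not pass edgeR. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give, so that test could not pass. The log2 fold change of Ccl8 was 4.83 without P16lo 1, but 2.24 without P16lo 2, 2.38 without P16lo 3 and 1.91 without P16hi 1. Among the other chemokines, Cxcl13, which attracts B cells, had a log2 fold change of 4.30 (SE 1.25), with 244 CPM in P16hi library 3 and 12.5 to 15.3 CPM in the other P16hi libraries, and 1.59 without library 3. Cxcl9, a ligand of the lymphocyte receptor Cxcr3, had a mean of 18.5 ± 14 CPM in P16lo and 105 ± 92.4 CPM in P16hi cells (n = 3), with overlapping libraries. Over all genes and adjusted over the list alone, 0 of 28 chemokines passed, the list median was -0.21, and camera gave an adjusted p of 0.21. The list of ligands that attract or activate cytotoxic lymphocytes had a median of -0.55 (camera adjusted p = 0.95).

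The clearest group difference in PDGFRα-high cells was in heart muscle genes. All 17 measured cardiomyocyte markers were higher in each P16hi library than in every P16lo library, with a median log2 fold change of 4.26. Actc1, cardiac α-actin, had 82.6 ± 10.2 CPM in P16lo and 1641 ± 829 CPM in P16hi cells (SD, n = 3). Myl3, the ventricular light chain, had 28.9 ± 4.11 and 619 ± 333 CPM, and Mb, myoglobin, 24.0 ± 2.15 and 505 ± 280 CPM. Over all genes 0 of the 17 passed edgeR, and adjusted over the list alone 17 did. DESeq2 called 16 and limma on log2(TPM + 1) 15 of them over all genes. Without P16hi 3, Actc1, Myl3 and Mb passed edgeR over all genes (adjusted p = 0.0314 each). They did not pass without P16lo 1, P16lo 2, P16lo 3 or P16hi 1 (edgeR adjusted p = 0.179, 0.485, 0.163 and 0.303 for each gene). Camera called the list higher (adjusted p = 3.1e-63), but not with an estimated correlation (adjusted p = 0.27 with an estimated correlation). The summed level of the list was 373 to 507 CPM in P16lo and 10920, 6887 and 3041 CPM in P16hi libraries 1 to 3. Per the labels, cardiomyocytes had been removed before the sort.

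Endothelial genes were also higher in P16hi PDGFRα-high cells. Of 15 markers, 13 had each P16hi library above each P16lo library, and the median log2 fold change was 1.78. Egfl7, a factor secreted by endothelium, had 112 ± 53.7 CPM in P16lo and 571 ± 33.8 CPM in P16hi cells (SD, n = 3), Emcn, endomucin, 77.6 ± 22.4 and 262 ± 33.5 CPM, and Esam, an adhesion molecule of endothelial junctions, 63.5 ± 14.9 and 234 ± 82.9 CPM. Over all genes 0 of the 15 passed, and adjusted over the list alone 13 did, while DESeq2 and limma on log2(TPM + 1) each called 9 over all genes. Camera's call (adjusted p = 1.5e-21) was lost with an estimated correlation (adjusted p = 0.37 with an estimated correlation). Fabp4, which is both an endothelial marker here and a gene of lipid-handling macrophages, had a log2 fold change of 2.77 (SE 0.757), and Cd36, a fatty acid and scavenger receptor, 2.26 (SE 0.653). Klf2, a transcription factor of endothelium, and the small heat shock gene Hspb1, both taken from the list of genes induced by tissue dissociation, had log2 fold changes of 1.79 (SE 0.392) and 2.19 (SE 0.55).

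Monocyte, T and NK cell, neutrophil, erythroid and mitosis lists were called lower in P16hi PDGFRα-high cells. The list of monocyte and recruited macrophage genes had a median log2 fold change of -1.73 with 24 of 24 members below 0, mitosis genes -1.78 with 29 of 30, T and NK cell markers -1.84 with 18 of 18, neutrophil markers -1.87 with 9 of 12, and erythroid markers -3.89 with 7 of 7. Much of this lay in P16lo library 2, which had 2177 CPM of Chil3, a chitinase-like protein of monocytes, against 32.5 and 32.3 CPM in the other P16lo libraries, and 231 CPM of Cd8a, the coreceptor of cytotoxic T cells, against 2.48 and 20.3 CPM. S100a9, a calcium-binding protein of neutrophils, had 457 CPM there, and Mki67, a marker of dividing cells, 101 CPM. Without P16lo library 2 the medians were -0.38 for mitosis (adjusted p = 0.2), -0.42 for T and NK cells (0.85) and -0.17 for neutrophils (0.91), and the monocyte median was -0.68 (0.012, still called). The erythroid median was -2.35 without P16lo 3 and the T and NK median -3.69 without P16hi 3. Hemoglobin genes took 0.587%, 18.6% and 44.8% of the counts of P16lo libraries 1 to 3 and 0.244%, 4.61% and 2.49% of those of P16hi libraries 1 to 3. Each of these lists was called by camera (adjusted p from 2.5e-06 for mitosis to 0.045 for neutrophils), and each call was lost with an estimated correlation (adjusted p = 0.76 to 0.78 with an estimated correlation). Adjusted over the list alone, 1 monocyte gene and 0 members of the other lists passed; over all genes 0 did.

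Resident macrophage, lipid-handling and interferon lists were called modestly higher in P16hi PDGFRα-high cells, while their summed levels overlapped between the groups. Resident genes summed to 4473, 484.5 and 1092 CPM in P16lo and 3387, 2962 and 2265 CPM in P16hi libraries 1 to 3. The resident cardiac macrophage list had a median log2 fold change of 0.56, with 13 of 15 members above 0, among them Lyve1 (1.65, SE 0.583) and the lectin gene Fcna (2.87, SE 1.08; 4.91 without P16lo 1). Lipid-handling macrophage genes had a median of 0.81, interferon-stimulated genes 0.44 with Gbp2 (2.80, SE 0.785; 1.56 without P16hi 3) and Cmpk2 (1.45, SE 0.398), MHC class I presentation 0.48 with Psmb9 (1.04, SE 0.402), and complement 0.23. The medians of the remaining lists were 0.64 for oxidative phosphorylation and 2.4 for mesothelial and glial markers. Oxidative phosphorylation genes summed to 8176, 9946 and 7396 CPM in P16lo libraries 1 to 3. In P16hi libraries 1 to 3 they summed to 17360, 12210 and 8328 CPM, with P16hi 3 below P16lo 2. The P16hi order was that of the cardiomyocyte genes (10920, 6887 and 3041 CPM). Camera called each higher (adjusted p from 1.8e-08 to 0.012), each call was lost with an estimated correlation (adjusted p = 0.76 to 0.79 with an estimated correlation), and 0 members of these lists passed over all genes or adjusted over the list alone. Single libraries carried several of these calls: without P16hi library 3 the interferon median was -0.10 (adjusted p = 0.76), MHC class I 0.08 (0.32), complement -0.03 (0.11) and mesothelial and glial markers 0.71 (0.16), and without P16hi library 1 the lipid-handling median was -0.31 (0.48) and complement 0.04 (0.066). Called values that moved were the resident list (2.16 without P16lo 1, 0.26 without P16lo 2), lipid-handling genes (1.57 and 0.52), interferon (0.82 without P16lo 2, 0.78 without P16hi 1), MHC class I (0.77 without P16lo 2) and complement (0.42 without P16lo 3). Without P16lo library 3 interferon (0.29) and MHC class I (0.38) were also not called, nor complement without P16lo library 2 (median -0.22, adjusted p = 0.098) or with at least 50 counts in 3 libraries (0.062). Ribosomal protein genes (-0.35, adjusted p = 0.0028) and NF-kB targets (-0.58, adjusted p = 0.044) were called lower, and these calls too were lost with an estimated correlation (adjusted p = 0.87 and 0.78 with an estimated correlation). Without P16lo 2, P16hi 2 or P16hi 3 the ribosomal list was not called (adjusted p = 0.096, 0.069 and 0.47), and without P16hi 1 its median was -0.59. With library totals only its median was 0.01 and the call was lost (adjusted p = 0.07). Nor were NF-kB targets called without P16lo 1, P16lo 2, P16hi 1 or P16hi 2 (0.31, 0.095, 0.076 and 0.14) or with the replicate number as a block (0.074). Neutrophil markers were also not called without P16hi 2 (0.27).

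No senescence or fibroblast list passed its test in PDGFRα-high cells. The p16, p53 and arrest list had a median of -0.48, with Ccng1, a p53 target, at 60 ± 13.3 CPM in P16lo and 140 ± 58.0 CPM in P16hi cells (SD, n = 3), and Gadd45b, a stress-induced gene, at 181 ± 123 and 54.5 ± 26.2 CPM. Factors secreted by senescent cells had a median of -0.24, collagens and matrix -0.92, fibroblast markers -0.97, resting fibroblast genes -1.25, TGF-β response genes -0.73 and contractile myofibroblast genes -0.48. The matrix, fibroblast and resting fibroblast lists had their highest sums in P16lo library 3. Fibroblast markers summed to 778, 2814 and 22910 CPM in P16lo and 4811, 2048 and 7829 CPM in P16hi libraries 1 to 3. For resting fibroblast genes these were 1389, 2467 and 18640 against 3020, 2702 and 8177 CPM, with every P16hi library above P16lo 1 and 2. Id1, a target of BMP and TGF-β signalling, had a log2 fold change of 2.53 (SE 0.421), and Tpm1, a tropomyosin of muscle and contractile cells, 2.70 (SE 0.568). Each was the 1 member of its list that passed when adjusted over the list alone. Other medians were -0.63 for DNA replication, -0.88 for MHC class II, -0.16 for phagocytosis receptors, -0.15 for lysosomal genes, 0.28 for glycolysis and hypoxia (Bnip3 1.42, SE 0.341), -0.11 for dissociation genes, -0.12 for macrophage, 0.03 for pericyte and smooth muscle, -1.78 for B cell and -1.15 for dendritic cell markers. The camera adjusted p of these lists ran from 0.059 upward. For 7 lists, all uncalled, the median was below 0 and camera's direction was up: chemokines, cytotoxic ligands, secreted factors, myofibroblast, phagocytosis, dissociation and macrophage genes.

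Over all 13262 genes tested in PDGFRα-high cells, edgeR called 0 higher and 0 lower, with 637 higher and 222 lower at an unadjusted p under 0.05. These were 1168 and 31 with library totals only and 1286 and 11 with limma on log2(TPM + 1), so their balance depends on the scaling. The smallest adjusted p was 0.0838, shared by 22 genes that were all higher, led by Ldb3 (gene 24131, chromosome 14, 34526699 to 34590314), a Z-disc protein with a log2 fold change of 4.62 (SE 0.49), Myoz2, another Z-disc protein (3.95, SE 0.472), and Actc1 (4.31, SE 0.521). The smallest p among lower genes were those of Thbs1, thrombospondin 1 (-2.53, SE 0.537), E2f2 (-2.68, SE 0.681) and Snx18 (-1.18, SE 0.312). Groups did not overlap for 1050 genes higher and 918 lower, 14.8% of the genes tested, where chance gives 10%. DESeq2 called 293 higher and 11 lower, limma on log2(TPM + 1) 263 and 0, edgeR with library totals only 39 and 0 and without the low-count filter 23 and 0. Without P16hi library 3 edgeR called 17 higher, and the count lower at an unadjusted p was 92 without P16lo 2, 94 without P16hi 2 and 528 without P16lo 3. Camera called 9 lists higher and 7 lower, of which 0 held with an estimated correlation or by fry. Without P16lo 1 it called 14 and 12, without P16hi 3 it called 5 higher, and the number lower was 3 without P16lo 2 and 11 without P16lo 3.

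**Figure D2:**
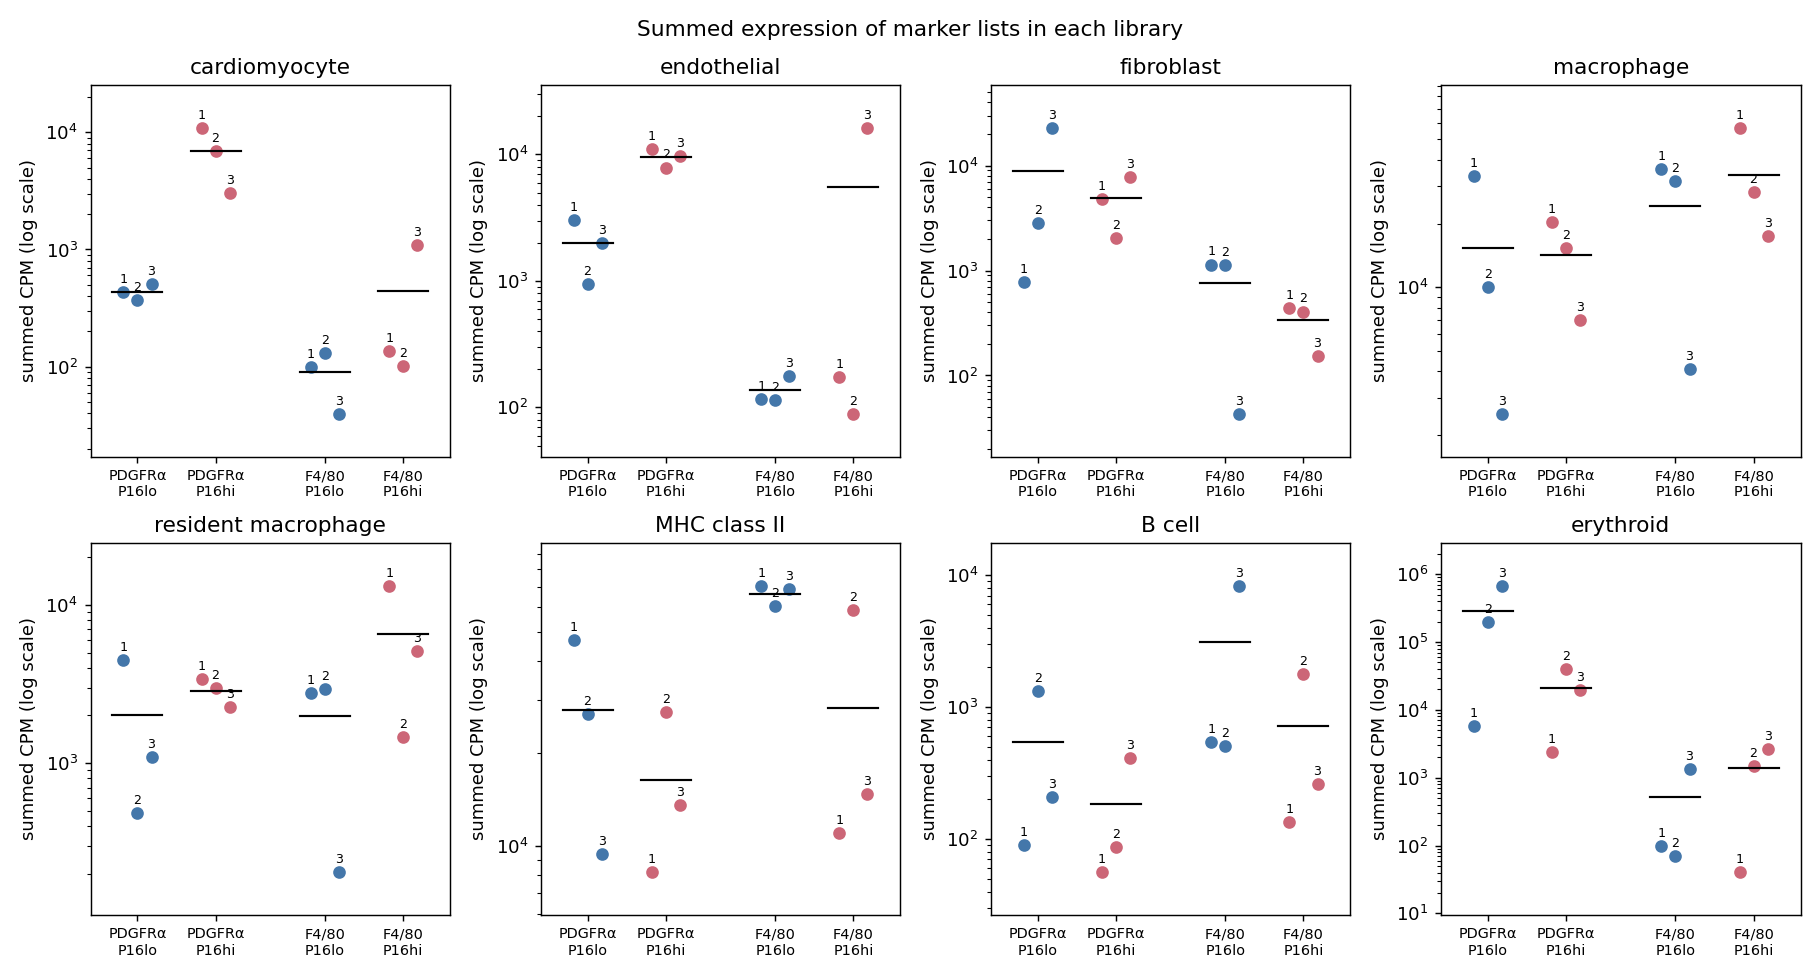
Summed CPM on a log scale of 8 marker lists in each library, as points numbered by replicate, with a line at the mean of each group of 3. Cardiomyocyte genes lay at 373 to 507 CPM in PDGFRα P16lo and 3041 to 10920 CPM in PDGFRα P16hi libraries; endothelial genes reached 16240 CPM in F480 P16hi library 3, against 89.3 to 178 CPM in the other F480 libraries.

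In F480-high cells, the non-overlapping genes with the smallest p were Mgst1, F13a1 and Gyg among those higher and Pkmyt1, Stap1 and Icosl among those lower in P16hi libraries. Mgst1, a microsomal glutathione transferase (gene 56615, chromosome 6, 138140527 to 138156755), had 30.6 ± 2.05 CPM in P16lo and 159 ± 46.9 CPM in P16hi cells (SD, n = 3). F13a1, coagulation factor XIII A (gene 74145, chromosome 13, 36867178 to 37050244), had 112 ± 39.7 and 481 ± 119 CPM, and Gyg, glycogenin, 68.5 ± 9.34 and 170 ± 50.7 CPM. Pkmyt1, a kinase that restrains entry into mitosis (gene 268930, chromosome 17, 23726336 to 23736735), had 26.4 ± 1.37 and 6.76 ± 1.88 CPM, Stap1, a signalling adaptor, 148 ± 30.1 and 59.1 ± 5.26 CPM, and Icosl, the ligand of the T cell costimulator ICOS, 121 ± 31.9 and 37.3 ± 15 CPM. These 6 did not overlap between groups and did not pass edgeR (adjusted p = 1.0 each). DESeq2 called Mgst1 (log2 fold change 2.4, adjusted p = 1.1e-06), F13a1 (2.12, 0.0089) and Pkmyt1 (-1.94, 0.0018).

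Ccl8 varied widely among F480-high libraries. It had 42.7, 30.5 and 0.916 CPM in P16lo and 2000, 1.72 and 429 CPM in P16hi cells, a log2 fold change of 5.04 (SE 2.26) with an edgeR adjusted p of 1.0 and an exact permutation p of 0.4, and 3.11 without P16hi 1. Within the column block of P16lo 3, P16hi 2 and P16hi 3, Ccl8 had 0.916 CPM in P16lo and a mean of 215 CPM in P16hi cells, and within the other block a mean of 36.6 CPM in P16lo and 2000 CPM in P16hi cells. With the block as a covariate, a choice made after the data were seen, its log2 fold change was 6.77 (SE 2.1, edgeR adjusted p = 0.72). Cxcl12 had 523 CPM in P16hi library 3 and 0.229 to 8.68 CPM in the other F480 libraries, and its log2 fold change went from 4.97 to -0.28 without that library. The chemokine list had a median of 0.15, the cytotoxic ligand list -0.23 and the senescence-associated secreted factors 0.21, with camera adjusted p of 0.14, 0.23 and 0.13.

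In P16hi F480-high cells resident macrophage genes were called higher and MHC class II and DNA replication genes lower, by camera with the preset correlation only. The resident list had a median log2 fold change of 1.56 with 16 of 16 members above 0, among them Gas6 (2.88, SE 1.68), a ligand for the uptake of dying cells, and Mrc1, the mannose receptor (1.41, SE 1.28), both with overlapping libraries. Without P16hi 1 they had 1.69 and 0.37, and Mrc1 had 0.84 without P16lo 3. MHC class II genes had a median of -1.33 with 11 of 11 below 0. H2-Eb1 had 7007 ± 662 CPM in P16lo and 2209 ± 2306 CPM in P16hi cells (SD, n = 3), and H2-Aa 11750 ± 1265 and 3851 ± 4224 CPM. P16hi library 2, with 58730 CPM of summed MHC class II genes against 11030 and 14790 CPM in P16hi 1 and 3, also had the most B cell (1768 against 134 and 261 CPM) and dendritic cell markers (1500 against 61.8 and 319 CPM) of the P16hi libraries. In P16lo libraries 1 to 3 MHC class II genes summed to 70480, 60540 and 68840 CPM, B cell markers to 546, 511 and 8259 CPM and dendritic cell markers to 718, 697 and 2416 CPM. DNA replication genes had a median of -0.82 with 27 of 28 below 0, including the helicase subunits Mcm2 (-1.31, SE 0.363), Mcm5 (-1.21, SE 0.37) and Mcm7 (-0.99, SE 0.323), and ribosomal protein genes -0.44 with 51 of 51. Camera called the 4 lists (adjusted p = 1.6e-08, 3.7e-08, 3e-09 and 2.2e-07) and each call was lost with an estimated correlation (adjusted p = 0.85, 0.85, 0.85 and 0.88 with an estimated correlation). Adjusted over the list alone, 1 resident gene and 0 members of the other lists passed; over all genes 0 did. Without P16lo 3 the medians were 0.98 for the resident list, -0.52 for MHC class II and -0.22 for ribosomal proteins, without P16hi 1 the resident median was 0.61 and without P16hi 2 that of MHC class II -2.97, all still called. In each column block every P16hi library was above every P16lo library for Cdkn2a, Mgst1, F13a1, Ccl8, the summed resident list (15.9-fold and 4.61-fold) and Adgre1 (8.75-fold and 1.32-fold). It was below for the summed MHC class II (0.534 and 0.168), DNA replication (0.682 and 0.653) and B cell genes (0.123 and 0.253). A block has a single library on 1 side, and of all tested genes 17.5% were higher and 17.7% lower in both blocks. Chance gives 11.1% per direction if the libraries are interchangeable. P16lo 1 and 2, which share a block, were not, with a Spearman correlation of 0.991 with each other. The chance share is therefore above 11.1%, and an excess over it was not shown. Across all 6 libraries the summed resident list overlapped (2756, 2960 and 205 CPM in P16lo, 13160, 1454 and 5077 CPM in P16hi).

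Endothelial and cardiomyocyte genes were high in a single F480-high library. Endothelial markers summed to 16240 CPM in P16hi library 3, against 89.3 to 178 CPM in the other libraries, and cardiomyocyte markers to 1089 CPM against 39.7 to 137 CPM. Flt1, a VEGF receptor, had 708 CPM there and 1.82 to 7.45 CPM elsewhere. Tek, a receptor of endothelium, had 207 against 0.381 to 1.83 CPM, Esam 445 against 1.15 to 3.41 CPM, Fabp4 6863 against 7.91 to 65.1 CPM, Cd36 2508 against 24.1 to 248 CPM, and Actc1 193 against 0.611 to 8.24 CPM. The list medians were 6.47 and 4.96 (camera adjusted p = 4.2e-09 and 1.2e-07), both lost with an estimated correlation (adjusted p = 0.85 for each with an estimated correlation), and the medians were 0.34 (adjusted p = 0.21) and 0.53 (adjusted p = 0.033) without that library. Pericyte and smooth muscle markers, with a median of 2.46, also had most of their counts there (349 CPM against 4.81 to 23.7 CPM), and without it the median was 0.12 (adjusted p = 0.81). Adjusted over the list alone and over all genes, 0 members of these lists passed.

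A further 7 lists were called in F480-high cells, and the calls of all but the dissociation list were lost without 1 or another library. Lipid-handling macrophage genes had a median of 0.75, phagocytosis receptors 0.32, dissociation genes 0.49 (Jun 1.99, SE 0.742, and Fos 1.31, SE 0.502) and erythroid markers 1.34, all called higher by camera (adjusted p = 6.6e-05, 0.012, 6.6e-05 and 0.04). These calls were lost with an estimated correlation (adjusted p = 0.88, 0.88, 0.85 and 0.88 with an estimated correlation). Mitosis genes (-0.77; Ndc80, a kinetochore gene, -1.94, SE 0.686), B cell markers (-2.04) and MHC class I genes (-0.20) were called lower (adjusted p = 2e-04, 4.1e-05 and 0.04), and these calls too were lost (adjusted p = 0.88 for each with an estimated correlation). The highest B cell level was that of P16lo library 3, with 2565 CPM of the B cell receptor gene Cd79a against 150 and 199 CPM in the other P16lo libraries. Without that library the B cell median was 0.52 (adjusted p = 0.46), phagocytosis -0.20 (0.065), pericyte markers 1.5 (0.41) and lipid-handling genes 0.21 (0.95), and without P16hi 1 the lipid-handling median was -0.39 (0.53), phagocytosis -0.39 (0.99) and B cell -1.6 (0.07). Mitosis genes were not called without P16lo 1, P16lo 2 or P16hi 3 (adjusted p = 0.11, 0.15 and 0.055), and erythroid markers not without P16lo 1, P16lo 2, P16hi 2 or P16hi 3 (0.19, 0.27, 0.38 and 0.62), nor with library totals only (0.051) or no low-count filter (0.091). Without P16lo 3 and P16hi 3 together the dissociation (0.11), lipid-handling (0.52), phagocytosis (0.87) and MHC class I lists (0.14) were not called. MHC class I was not called without P16lo 1, P16lo 2, P16hi 1 or P16hi 3 (0.19, 0.08, 0.06 and 0.44). With the column block as a covariate camera did not call mitosis genes (median 0.17, adjusted p = 0.46) or erythroid markers (-0.23, 0.46). Nor did it then call MHC class I genes (-0.18, 0.19) or pericyte markers (2.99, 0.055). Medians that moved with the call kept were mitosis (-1.26 without P16lo 3, -1.34 without P16hi 2), dissociation (0.26 without P16hi 3), B cell (-4.73 without P16hi 2), erythroid (3.6 without P16lo 3) and MHC class I genes (-0.32 without P16lo 3, -0.40 without P16hi 2). Lipid-handling genes had 1.13, 1.19 and 1.23 without P16lo 1, P16lo 2 and P16hi 2, and phagocytosis 0.53, 0.81, 0.66 and 0.71 without P16lo 1, P16lo 2, P16hi 2 and P16hi 3.

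Of these 7 lists in F480-high cells, 0 members passed over all genes or adjusted over the list alone. The median of the arrest list was 0.24, collagens -1.16, fibroblast markers -1.02, resting fibroblast genes 0.24, myofibroblast genes 0.84, TGF-β response 0.17, interferon -0.06, NF-kB targets -0.10, complement 0.12, monocyte genes 0.41, lysosome 0.17, oxidative phosphorylation 0.05, glycolysis 0.08, macrophage markers 0.09, T and NK 0.02, neutrophil -0.06 and dendritic cell markers 0.24, with camera adjusted p from 0.079 upward. Mesothelial and glial markers had 4 tested members and no list test. The median and camera's direction differed in sign for interferon and dendritic cell genes, and the median and mean for NF-kB, complement, T and NK, neutrophil and cytotoxic ligand genes.

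Over all 12490 genes tested in F480-high cells, edgeR called 0 higher and 0 lower, with 242 higher and 38 lower at an unadjusted p under 0.05 and a smallest adjusted p that rounds to 1.0. The unadjusted counts were 50 and 57 with the replicate block, 52 and 57 with limma-voom and 92 and 48 with limma on log2(TPM + 1), so the excess of higher genes depends on the method. DESeq2 called 2 higher and 1 lower, and limma on log2(TPM + 1) 0 and 0. Groups did not overlap for 421 genes higher and 435 lower, 6.85% of the genes tested, where chance gives 10%. The counts at an unadjusted p were 42 and 22 without P16lo 1, 39 and 20 without P16lo 2, 74 and 123 without P16lo 3, 461 and 81 without P16hi 1, 563 and 345 without P16hi 2, and 69 and 32 without P16hi 3. With the column block as a covariate edgeR called 0 and 0, with 511 higher and 348 lower at an unadjusted p and a smallest adjusted p of 0.493. Camera called 8 lists higher and 6 lower, of which 0 held with an estimated correlation or by fry. It called 13 higher without P16lo 2 and 17 lower without P16lo 3.

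**Figure D3:**
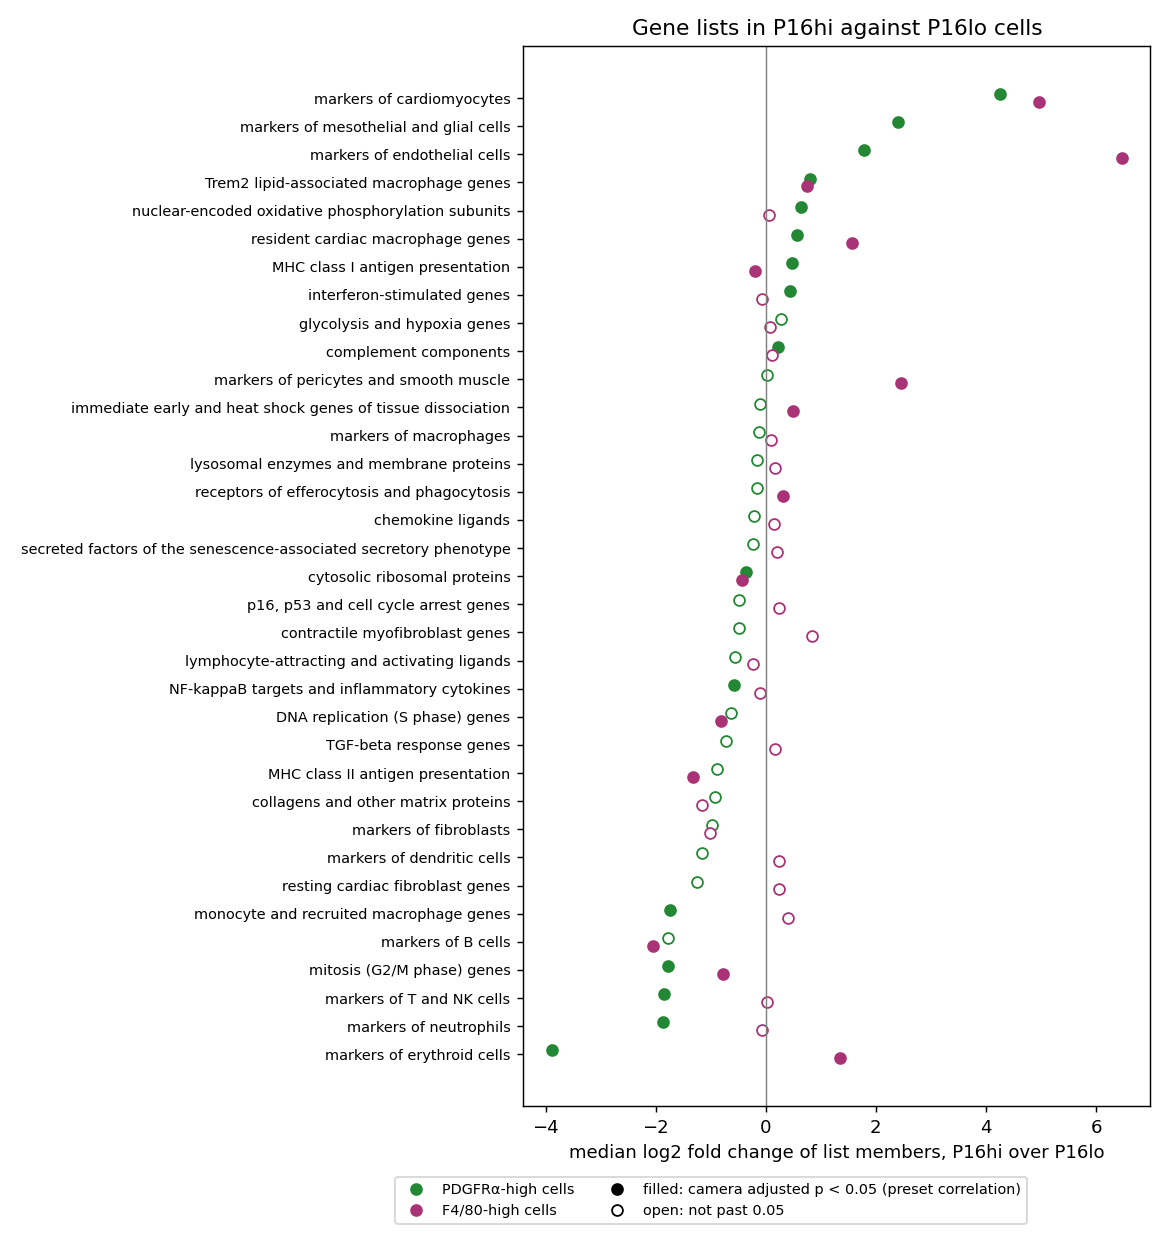
Median log2 fold change of the members of each tested gene list, P16hi over P16lo, in PDGFRα-high (green) and F480-high (purple) cells; filled points passed camera with the preset correlation. Cardiomyocyte markers lay at 4.26 and 4.96 and erythroid markers at -3.89 and 1.34, and 0 lists held with an estimated correlation.

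The difference between P16hi and P16lo was then compared between the sorted populations. Etfdh, Hadhb and Eci1, which each encode an enzyme of mitochondrial fatty acid oxidation, had log2 fold changes higher in PDGFRα-high than in F480-high cells, by 1.57 (SE 0.416), 1.83 (SE 0.552) and 1.75 (SE 0.552). Cardiomyocyte markers were also higher in all 3 P16hi libraries of PDGFRα-high cells (median 4.26) and high in only 1 library of F480-high cells, and no list of fatty acid oxidation genes was tested. For Ada, adenosine deaminase, and Mgst1 the value in PDGFRα-high minus that in F480-high cells was -1.95 (SE 0.574) and -2.02 (SE 0.601). Ada had opposite signs in the populations. Over 14073 genes edgeR called 0 higher and 0 lower (adjusted p = 1 for each gene named here), with 113 and 186 at an unadjusted p under 0.05, and DESeq2 called 1 and 7. The unadjusted counts were 233 and 89 with library totals only and 589 and 6 with limma on log2(TPM + 1). Of the unadjusted counts, those higher were 173, 198 and 240 without PDGFRα P16hi 3, F480 P16hi 2 and F480 P16hi 3, and those lower 100, 110, 102, 91, 122, 383 and 353 without PDGFRα P16hi 1 and 2, F480 P16lo 1, 2 and 3 and F480 P16hi 1 and 2. The median over all genes was -0.17 in PDGFRα-high cells and -0.20 for this difference, and with library totals only 0.24 and 0.13. The directions of the genes named here held under each scaling.

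More genes were higher with P16 in both populations than independent calls would give, and the number depended on F480 libraries. At an unadjusted p under 0.05, 94 genes were higher in both, against 9 expected from independent calls among 12132 genes, and 2 were lower in both, against 0.6. Endothelial and muscle genes such as Egfl7, Emcn, Esam, Flt1, Actc1 and Myl3 were among the 94. The number was 5 without F480 P16hi 3, 6, 7 and 10 without F480 P16lo 1, 2 and 3, and 165 and 184 without F480 P16hi 1 and 2. The number lower in both was 0 without PDGFRα P16lo 2, P16hi 1 or P16hi 2, 6 without PDGFRα P16lo 3, 32 without F480 P16hi 2 and 1 without F480 P16hi 3. At the adjusted threshold 0 genes were shared, since edgeR called 0 in either population. Log2 fold changes correlated across genes with Pearson's r of 0.415 and Spearman's rho of 0.274, and r was 0.133 without F480 P16hi 3 and 0.253 without PDGFRα P16lo 2. Genes are not independent replicates.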

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

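Of the tests in this part, those of hemoglobin dilution and of expression by the sorted cells were chosen after the results they weigh were seen.

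Ada, adenosine deaminase, differed in opposite directions in the sorted populations, with every P16hi library on the same side of every P16lo library. The log2 ratio of mean CPM was -0.93 in PDGFRα-high cells and 1.08 in F480-high cells. Ada was named because its p for the difference between populations was among the 3 smallest in its direction. Opposite directions are partly a result of that choice. Groups did not overlap for 14.8% of the genes tested in PDGFRα-high and 6.85% in F480-high cells, so some genes take opposite sides by chance. The edgeR test of the difference itself gave an adjusted p of 1.

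The deposited TPM of F480 P16hi library 3, a column that the F480 comparison used only for the TPM alternative, had a Spearman correlation of 0.921 with its FPKM, where TPM and FPKM of the other libraries were proportional. The highest correlation with the TPM of another library, PDGFRα P16lo library 1, was 0.952, and a copy would give 1, which argues against a copied column. The ratio of TPM to FPKM had a correlation of -0.045 with the gene length behind the FPKM. This cannot decide on other gene lengths behind the TPM, since a change of length need not follow the length itself. Endothelial TPM computed from the FPKM were 4.12 times those in the TPM column (27200 against 6600), so the TPM may come from another RNA sample or sequencing run than the counts and FPKM, and which of them belongs to this library is open. Its Ccl8 was 746 in the TPM column and 1700 from the FPKM, its resident macrophage genes 1630 and 3390, MHC class II genes 31500 and 17400, Cdkn2a 0.89 and 1.45 and erythroid markers 22400 and 8570, so each printed F480 difference of these but the erythroid would shrink if the TPM were the right ones. No biological explanation was tested.

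Heart muscle genes were higher in all 3 P16hi PDGFRα-high libraries, although cardiomyocytes had been removed before the sort. With every library thinned to 3.16 M counts (M, 1000000) the median log2 fold change was 4.23. Thinning keeps each gene's share of its library, so this covers only the counting at lower depth. It cannot decide on causes that may go with low depth, such as the amount of input RNA, which were not tested. Dilution by hemoglobin can give at most 1.81-fold, a log2 of 0.86, below the smallest log2 fold change of the list, 1.91, and 0 of the 17 list genes are in another list. RNA carried in from cardiomyocytes, through fragments that stuck to sorted cells or through free RNA, stays open: the muscle genes kept nearly 1 set of proportions, with a largest SD of the log2 ratio between P16hi libraries of 0.59 (0.59% of 10000 random lists matched on expression were as tight). The abundant Actc1 averaged 1641 CPM in P16hi and 82.6 CPM in P16lo cells. The removal of cardiomyocytes before the sort need not have taken away fragments or free RNA. After it the P16lo libraries too held 373 to 507 CPM of the list. Expression by the P16hi cells themselves cannot be told apart from RNA carried in, since no value separates these sources. The summed level differed 3.59-fold among the P16hi libraries.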

How the results depend on the processing

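The column-block, hemoglobin, TPM, listed-gene and paired-exclusion settings, and the overlap without each library, were chosen after the data were seen. Counts of genes past edgeR were 0 in most settings, which says little, since 0% to 3% of simulated 4-fold changes were called. For the same reason, a gene that passed in no setting is not shown to be stable. Leaving out 1 library, camera kept its call and direction for cardiomyocyte (3.64 to 4.59), endothelial (1.51 to 2.09) and monocyte genes (-2.13 to -0.68) in PDGFRα-high cells and for resident macrophage (0.61 to 2.08), MHC class II (-2.97 to -0.52) and DNA replication genes (-1.06 to -0.64) in F480-high cells. F480 P16lo 1 and 2 were nearly alike (Spearman correlation 0.991), so leaving out either of them tests little. In PDGFRα-high cells genes higher were 39 with library totals only, 23 with no low-count filter, 293 with DESeq2 (11 lower) and 263 with limma on log2(TPM + 1), and 0 to 17 leaving out 1 library. Lists higher and lower were 0 with an estimated correlation and 0 by fry; lists lower were 13 without P16lo 1 and P16hi 1 together, and leaving out 1 library gave 5 to 14 higher and 3 to 12 lower. In F480-high cells DESeq2 called 2 higher and 1 lower; lists were 0 with an estimated correlation and 0 by fry, 10 lower with the replicate block, 2 higher and 14 lower without P16lo 3 and P16hi 3 together, 15 higher with the column block as a covariate, and 6 to 13 higher and 4 to 17 lower leaving out 1 library. For the difference between populations DESeq2 called 1 and 7. Genes higher in both populations were 40 with at least 50 counts in 3 libraries and 5 to 184 leaving out 1 library; genes lower in both were 9 by DESeq2 and 0 to 32 leaving out 1 library, with Pearson's r from 0.133 to 0.462. Medians that changed sign in PDGFRα-high cells were ribosomal proteins (0.01 with library totals only) and, leaving out 1 library, complement (-0.22 to 0.42), lipid-handling macrophage (-0.31 to 1.57) and interferon genes (-0.10 to 0.82). In F480-high cells these were, without P16lo 3 and P16hi 3 together, Cxcl12 (-0.84), Cd79a (0.50), pericyte (-0.29) and B cell markers (0.83), with the column block mitosis (0.17) and erythroid genes (-0.23), and leaving out 1 library Cxcl12 (-0.28 to 5.55), Cd79a (-5.20 to 0.05), phagocytosis (-0.39 to 0.81), B cell (-4.73 to 0.52) and lipid-handling genes (-0.39 to 1.23). The block by replicate number was fitted, but except for number 3 of PDGFRα, P16hi and P16lo libraries of the same number were not each other's closest, so a pairing by number was not shown, nor was it excluded. Fewer libraries explain part of the leave-out changes by construction; the cause of the others was not tested. Depth limits the precision of Cdkn2a, at 2 to 26 counts per library.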

Other observations

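Among the tests in this part, those of Ccl8 against resident and all macrophages, and the column block as a covariate, were chosen after the results were seen; the other splits and the resident covariate were not.

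Libraries of the same P16lo group differed in their markers of cell types. PDGFRα P16lo library 3 had the most fibroblast transcripts, with 22910 CPM of summed fibroblast markers, and 44.8% hemoglobin counts; PDGFRα P16lo library 1 had 33620 CPM of macrophage markers and 778 CPM of fibroblast markers. In F480-high cells P16lo library 3 had 4123 CPM of macrophage markers and 8259 CPM of B cell markers, against 31960 to 36330 and 511 to 546 CPM in P16lo libraries 1 and 2, which had a Spearman correlation of 0.991 with each other. MHC class II genes nevertheless summed to 60540 to 70480 CPM in all 3.

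By Pearson's r, Ccl8 followed resident macrophage genes in F480-high cells, and in PDGFRα-high cells only through P16lo 2 and P16lo 3. Across 6 libraries its log2 CPM had Pearson's r of 0.90 with the summed resident list, which does not hold Ccl8 and shares 4 of its 17 genes with other lists, in each population (exact permutation p = 0.019 and 0.0083, adjusted p = 0.038 and 0.033 over 4 relations), and Spearman's rho of 0.6 and 0.94 (exact p = 0.24 and 0.017, adjusted 0.3 and 0.068). In PDGFRα-high cells r was -0.11 without P16lo 2 and P16lo 3, so it rests on these, and in F480-high cells 0.99 without P16lo 3 and P16hi 1. Adgre1, for all macrophages, gave r of 0.71 and 0.69 (exact p = 0.12 and 0.14, adjusted 0.14 each), which does not decide. With the resident list as a covariate the log2 fold change of Ccl8 was 2.16 (SE 0.61) in PDGFRα-high and 0.94 (SE 1.82) in F480-high cells. In F480-high cells it was 5.04 (SE 2.26) without a covariate and 6.77 (SE 2.1) with the column block instead. The resident list there correlated with P16 at 0.53, and the standard errors are wide. This fit cannot tell a share of resident macrophages in the F480 sort from P16 state. P16 state stays open in both populations. Mrc1, an abundant resident gene, ranged from 6.26 to 952 CPM in F480-high cells. The PDGFRα gate is meant to leave such cells out and the F480 gate to keep them. The PDGFRα libraries nevertheless held 2523 to 33620 CPM of summed macrophage markers, beside 4123 to 56770 CPM in the F480 libraries.

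Other splits of the 6 libraries are too few for a share under 0.05. In PDGFRα-high cells the real split gave 859 genes at an unadjusted p and the highest other 1082 (4 of 10 splits as large), DESeq2 304 against 312 (3 of 10), limma on log2(TPM + 1) 263 against 108 (1 of 10), camera 16 lists against 26 (8 of 10), and genes past adjusted p 0 against 0 (10 of 10). In F480-high cells these were 280 against 2053 (7 of 10), DESeq2 3 against 963 (5 of 10), camera 14 lists against 24 (8 of 10) and 0 against 0 past adjusted p (10 of 10). The F480 split with 2053 and 963 genes parts the libraries by the column blocks of their table, a structure of the samples apart from P16; with the block as a covariate 511 genes were higher and 348 lower with P16 at an unadjusted p, and 0 passed. For the difference between populations chance cannot be excluded: 97 of 100 relabellings gave at least the 299 genes at an unadjusted p (highest other 2188). The real count past adjusted p was 0 (highest other 2). Every split or relabelling reaches a count of 0, so the counts past adjusted p cannot decide, here or within the populations.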
